A study of Mus musculus with 6 samples.

How the data were processed

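RNA was measured by sequencing in 6 libraries of mouse bone marrow LSK cells, the fraction without lineage markers that carries Kit and Sca1 on its surface and holds haematopoietic stem cells and early progenitors. The labels name 3 libraries as Arid2 knockout (floxed Arid2 with the Mx1-Cre transgene) and 3 as control (Mx1-Cre alone). Mice were injected at 6 to 8 weeks of age with pIpC, a double-stranded RNA analogue that induces interferon and so switches on the Mx1 promoter, and cells were sorted 6 weeks later. Per the labels' protocols, total RNA was poly(A)-selected and made into libraries with a strand-specific kit. Nothing in the labels says which animals or litters the libraries came from, so p-values measure the spread between these libraries.

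The values analysed are the raw read counts per gene symbol that the authors deposited, as whole numbers with no normalization. STAR and the mm10 build are named in the submitters' processing notes. The STAR version, the counting tool, its annotation and its strand setting are not given in the sources used here. The table held 24063 symbols, of which 4092 had no read in any library, and no mitochondrially encoded symbol. Reads of overlapping genes, antisense partners and near-identical copies may therefore have been split or shared in a way that cannot be checked here. Counts of 28 tested symbols repeated those of another symbol in every library, among them the globin pairs Hbb-b1 and Hbb-bs, Hbb-b2 and Hbb-bt, and Hba-a1 and Hba-a2. Gene positions were taken from GENCODE mouse release M21 on the same assembly (GRCm38, mm10), where 22779 symbols matched by name, 869 through a synonym and 415 not to a single gene.

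Total counts ran from 12408966 to 28185678 reads per library. Pairs of libraries were compared by a chi-square statistic over genes, which was at least 10.7 per degree of freedom, so no library repeated another within sampling noise. Intervals cover the spread between libraries as the model estimates it.

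Genes were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr (minimum count 10, minimum total 15), which left 13679 symbols, libraries were scaled by TMM, and a quasi-likelihood F test was run with the group as the sole term. Adjusted p is the Benjamini-Hochberg value over all symbols tested, with a threshold of 0.05. CPM values were computed here from the deposited counts after TMM scaling, except those of Xist and the Y-linked genes, which are over the library total. Gene lists were fixed before the data were examined, as were the main test and the rule for named genes; 26 lists with at least 5 measured genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The lists covered SWI/SNF subunits; stem cell, lymphoid, myeloid, and megakaryocyte and erythroid priming genes; markers of mature neutrophils, of monocytes, macrophages and dendritic cells, of B and plasma cells, of T and NK cells, of erythroblasts, of mast cells and basophils, and of marrow stroma and endothelium; type I interferon, interferon gamma, NF-kB, immediate early, S phase, G2 and M phase, p53, Myc, glycolysis, oxidative phosphorylation, Hox and TGF-beta genes; and ribosomal protein and histone genes by symbol pattern. Sex-linked and sort gate genes were listed as checks of the samples and not tested as lists.

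Named genes are Arid2, the 12 with the highest and the 12 with the lowest log2 fold change among genes past the threshold with a mean of at least 1 log2 CPM and no overlap between the groups, and up to 4 members with the smallest p of each list that camera called or that the design singles out. Predicted gene models, pseudogenes, Xist and Y-linked genes were passed over. Of the 66 genes so named, 11 overlap another symbol of the table. Results for some genes that this rule takes are not reported here. Other genes that the text names were chosen after their values were seen.

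The scripts were tested on simulated counts for the knockout against control comparison, with 13514 genes in the test. edgeR recovered 79% of genes changed 2-fold and 95.9% of genes changed 4-fold, with 16 false calls among 189. The list test called 1 of 1 raised list and 0 of 26 lists of unchanged genes, with all genes simulated independently of each other. It therefore does not show how often unchanged lists are called when their genes vary together. Lists called in the data had estimated correlations of 0.25 (replication-dependent histones) to 0.8 (erythroblasts).

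Alternatives fixed beforehand were DESeq2 size factors and upper-quartile scaling in edgeR, no filter on low counts, a stricter filter (at least 1 CPM in at least 3 libraries), DESeq2 1.42.0, limma-voom with and without library weights, the replicate number as a block, each library left out in turn, an adjusted p under 0.1, a minimum absolute log2 fold change of 1, removal of ribosomal protein and sex-linked genes, a sex term, fry, and camera with an estimated correlation. Fits on female libraries, a replicate block with a sex term, the sex term for results other than the counts of genes, and repeated rows counted once were added after seeing the data.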

Results

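The series asked how gene expression in mouse haematopoietic stem and progenitor cells differs after conditional deletion of Arid2, a DNA-binding subunit of the PBAF form of the SWI/SNF chromatin remodelling complex. RNA of LSK cells sorted 6 weeks after induction was sequenced in 3 libraries labelled knockout and 3 control libraries. The libraries labelled knockout held 19292944, 24989866 and 12408966 counted reads for replicates 1 to 3, and the control libraries 16585201, 28185678 and 13950708.

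Arid2 (ENSMUSG00000033237, chromosome 15, 96287518 to 96404992, plus strand, mm10) was not lower in the libraries labelled knockout. Its level was 156 ± 6.2 CPM (SD, n = 3) against 155.8 ± 8.5 CPM (SD, n = 3) in controls, a log2 fold change of 0.00 with an SE of 0.06 and an edgeR adjusted p of 0.99. The 95% confidence interval of the ratio ran from 90.4% to 110.9%. Read counts over the whole gene do not show whether a floxed exon is missing from the transcript, so the gene-level value neither shows nor excludes deletion. The groups are called by their labels throughout, and every direction given below rests on those labels.

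**Figure D1:**
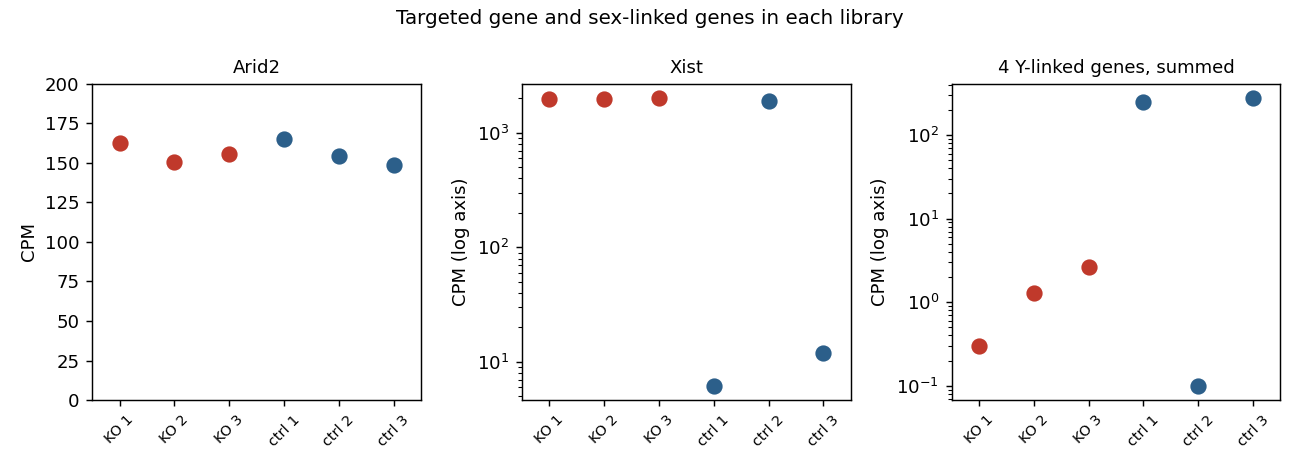
CPM of Arid2 (TMM-scaled, linear axis), Xist and the sum of 4 Y-linked genes (per library total, log axes) in each of the 6 libraries, 1 point per library, red for libraries labelled knockout (KO) and blue for control. Arid2 lies between 148.4 and 165 CPM in all 6, while control replicates 1 and 3 have Y-linked reads and little Xist.

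The sexes of the animals were unequal between the groups. All 3 libraries labelled knockout and control replicate 2 had 1916.4 to 2016.3 CPM of Xist, the RNA that coats the inactive X chromosome of females, whereas control replicates 1 and 3 had 6.2 and 11.9 CPM. Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) summed to 251.7 and 277.2 CPM in those same control libraries and to at most 2.6 CPM in the others. Control replicate 2 was the sole female control, so any fit that separates sex from the group rests on it. Of the genes behind the sort gate, Ly6a, which encodes Sca1, was 13.5 ± 1.6 against 20 ± 2.1 CPM (log2 fold change −0.56, SE 0.13, edgeR adjusted p = 0.0378, n = 3 each). That level is low for a gene of the sort gate, far below Kit, and how reads shared with related Ly6 genes were counted is not given in the sources used here, so what the Ly6a counts measure is uncertain. Kit was 439 ± 11 against 557.4 ± 86.1 CPM, and Ly6e, a related gene that does not encode Sca1 and is no part of the gate, 779.4 ± 53.7 against 833.2 ± 63 CPM, and neither passed the test (adjusted p = 0.0814 and 0.527).

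Between the groups, 526 genes were higher and 626 lower in the libraries labelled knockout, of 13679 tested (edgeR, adjusted p under 0.05). Marco, a scavenger receptor of macrophages, had 13.7 ± 7.8 CPM against 0.17 ± 0.098 CPM (SD, n = 3 each; log2 fold change 6.15, SE 0.58, edgeR adjusted p = 0.00251). The adult globin genes Hbb-bs (log2 fold change 3.79), Hba-a1 (3.15) and Hbb-bt (2.69) were higher as well, each with counts that a second symbol repeats, and so was Clec4n (2.91), which encodes the C-type lectin dectin-2. The other genes with the highest values were Cadm3 (3.11), a cell adhesion molecule whose gene overlaps Ackr1 and, on the opposite strand, Aim2, Maneal (3.02), Ugt8a (2.75), a galactosyltransferase of lipid synthesis, and Tchh (2.73).

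Among the decreases, the adhesion receptor gene Gpr128 (now Adgrg7) fell from 28 ± 5.1 to 2.8 ± 0.35 CPM (log2 fold change −3.34, SE 0.18, edgeR adjusted p = 0.000542, n = 3 each), with 32.6 CPM in female control replicate 2. Aldh1a7 had the lowest log2 fold change, −5.06, with 0.11 ± 0.12 against 4.4 ± 2.8 CPM and no read in knockout replicate 1. Further genes with low values were Mmp15 (log2 fold change −3.49), a membrane-bound matrix metalloproteinase, Bok (−3.29), a BCL2 family member, Car12 (−3.16), a carbonic anhydrase, Ptprf (−3.02), Islr (−2.77), Ehhadh (−2.75), an enzyme of peroxisomal fatty acid oxidation, Cd276 (−2.71), Btbd11 (−2.69) and the laminin gene Lamb2 (−2.69). Most of these had under 10 CPM in every library. The value of Lamb2 rests largely on control replicate 3, with 14.1 CPM against 5.1 and 2.1 in the other controls, and was −1.72 without it and −0.98 with the sex term (edgeR adjusted p = 0.57).

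**Figure D2:**
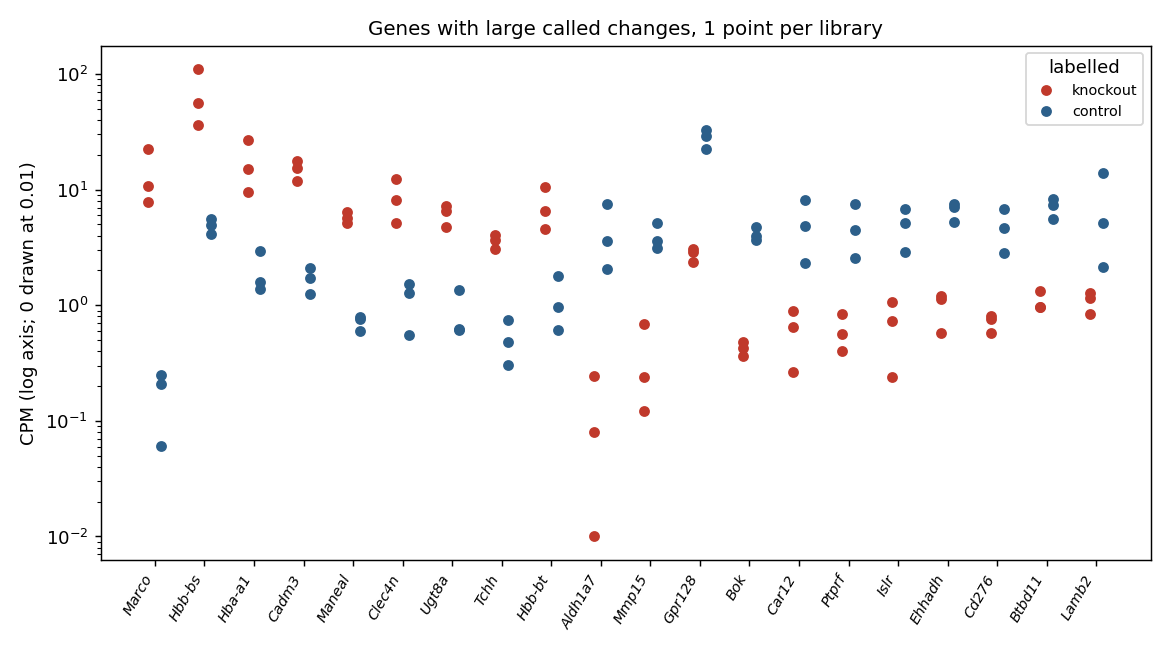
CPM (log axis, 0 drawn at 0.01) of genes with the largest called changes, 1 point per library, red for libraries labelled knockout and blue for control, with each pair of symbols that share counts drawn once. The points of the groups do not overlap for any gene drawn, because the rule for these genes required it. Means run from Marco at 13.7 against 0.17 CPM to Lamb2 at 1.1 against 7.1 CPM.

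The number of genes called depended on whether sex was modelled and on single libraries. With a sex term in the edgeR model, 7 genes were higher and 36 lower, and 3405 genes in the main test against 1633 with the sex term had an unadjusted p under 0.05. The fold change with the sex term compares the libraries labelled knockout with control replicate 2, the sole female control. Of the 1152 genes called by group alone, 42 stayed past the threshold with the sex term, among them Cadm3, Maneal, Gpr128, Bok, Car12 and Btbd11. Their direction was kept by 99.8% of the 1152, but 1150 of these had no overlap between the groups. That fixes the direction against control replicate 2 in advance, so the share says nothing about sex. For the 1152 genes, the ratio of the log2 fold change with the sex term to that without had a median of 0.87 (quartiles 0.76 and 1). Their median SE rose from 0.13 to 0.17. Control replicate 2 helped to make these calls, which can draw the ratio towards 1. Among 920 autosomal genes called without it, that library lay at a median of 0.32 of the way from the male controls to the libraries labelled knockout. Without knockout replicate 1, 2 or 3, or control replicate 1, the genes higher numbered 266, 119, 208 and 189 and the genes lower 264, 171, 300 and 284, and without control replicate 3 the genes lower numbered 409. Smarcc1, Blnk, Gbp5, Tapbp and Lamb2 lost their call in 5 of the 6 fits that leave out a library, and Hist3h2ba in all 6. Csf1r, Cebpb, Cd68, Stat2, Trim30a and Gp9 lost it in 4 of the 6.

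Of the 26 gene lists tested, camera called 6 higher and 3 lower in the libraries labelled knockout. The lists called higher included mature neutrophils (7 of 14 genes past the test), erythroblasts (7 of 13), monocytes, macrophages and dendritic cells (4 of 15) and myeloid priming (3 of 25), none of which was called with an estimated correlation (adjusted p = 0.71 each). Of 14 mature neutrophil genes, 7 were higher, 0 lower and 7 not past the test (10 higher when adjusted over the list alone; camera adjusted p = 1.04e-10, and adjusted p = 0.71 with an estimated correlation). Cd177, a neutrophil surface antigen, had 260.4 ± 28.8 against 92.6 ± 21.2 CPM (log2 fold change 1.49), and the granule protein genes Lcn2 and Ltf had log2 fold changes of 1.07 and 0.67, with Ifitm6 at 0.96. Not all members rose alike. Of the 7 not past the test, S100a8, S100a9 and Camp had 0.93, 0.89 and 0.83. Retnlg, Cxcr2, Mmp8 and Mmp9 had 0.353, 0.208, 0.023 and −0.135. Of 13 erythroblast genes, 7 were higher and 6 not past the test (7 adjusted over the list alone; camera adjusted p = 1.53e-09, and adjusted p = 0.71 with an estimated correlation). The median log2 fold change of the list was 1.34, and 2.82 with the sex term. Hba-a1 and Hba-a2, with a single set of counts, are both among those 7. Alas2, which starts haem synthesis in red cells, had 9.7 ± 5.7 against 1.5 ± 0.33 CPM, while Hbb-bs, the most abundant globin gene, reached 109.8 CPM in knockout replicate 3.

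Of 15 monocyte, macrophage and dendritic cell genes, 4 were higher and 11 not past the test (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 8.95e-08, and adjusted p = 0.71 with an estimated correlation). Among them were Lyz2, a lysozyme (1229 ± 46 against 752.6 ± 63.3 CPM, log2 fold change 0.71), the chemokine receptor Ccr2 (0.76) and Cd68 (0.69, and 0.45 with the sex term). All 25 myeloid priming genes had positive log2 fold changes by group alone and 6 had negative ones with the sex term, which took the median from 0.37 to 0.18. By group alone, 3 passed the test and 22 did not (6 adjusted over the list alone; camera adjusted p = 1.18e-06, and adjusted p = 0.71 with an estimated correlation). Those past the test were Sirpa (0.83), the macrophage colony-stimulating factor receptor Csf1r (0.66, and 0.39 with the sex term) and the transcription factor Cebpb (0.65, and 0.39 with the sex term). Csf2ra had a log2 fold change of 0.65 with an adjusted p of 0.0505 (0.43 with the sex term).

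The stem cell and lymphoid priming lists were called lower. Of 28 stem cell genes, 8 were lower, 1 higher and 19 not past the test (9 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00011, and adjusted p = 0.71 with an estimated correlation). Tie1, a receptor kinase of endothelial and stem cells, had 42.2 ± 6.4 against 88 ± 16.7 CPM (log2 fold change −1.06). Ctnnal1 (−1.47) and Robo4 (−1.36, and −0.75 with the sex term) were also lower, and the gene past the test in the other direction was Hoxb5 (1.34). The median of the stem cell list was −0.40, and −0.28 with the sex term, and 7 of the 28 genes were positive by group alone. Of those not past the test, Mecom had 0.23, Mllt3 0.21 and Hlf −0.002. Procr and Fgd5 had −0.40 and −0.47, but 0.215 and 0.224 with the sex term. Of 22 lymphoid priming genes, 4 were lower, 1 higher and 17 not past the test (8 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.000186, and adjusted p = 0.71 with an estimated correlation). Flt3, a receptor kinase that marks lymphoid-primed progenitors, had 238.7 ± 38.6 against 381.6 ± 51.7 CPM (log2 fold change −0.68, and −0.45 with the sex term). The median of the list was −0.47, and −0.25 with the sex term. Cnn3 had −2.24, while Blnk, an adaptor of B cell receptor signalling, was higher (0.68).

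Megakaryocyte and erythroid priming genes as a list were not called (camera adjusted p = 0.115, and 0.95 with an estimated correlation). The list was called with no filter on low counts (0.04), without knockout replicate 3 (0.000207) and without control replicate 1 (0.0108). Of 26 measured, 2 were lower and 24 not past the test (6 lower and 1 higher adjusted over the list alone). Itga2b, the integrin CD41, had 98.8 ± 22.6 against 187.5 ± 37.1 CPM (log2 fold change −0.93), and the platelet glycoprotein gene Gp9 had −1.27. Icam4 and Nfe2 had −0.67 and −0.25 (−0.13 with the sex term for Nfe2) and did not pass (edgeR adjusted p = 0.0518 and 0.0827).

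Both interferon lists were called higher by camera, though most members of each did not pass the test. Of 32 type I interferon genes, 6 were higher and 26 not past the test (8 adjusted over the list alone; camera adjusted p = 0.000186, and adjusted p = 0.71 with an estimated correlation). The RNA sensor Ifih1 had 67.7 ± 2.9 against 45.7 ± 5.2 CPM (log2 fold change 0.56), with Bst2 at 0.36, Stat2 at 0.34 and Trim30a at 0.30. Of 30 genes of the interferon gamma response and antigen presentation, 3 were higher, 1 lower and 26 not past the test (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00148, and adjusted p = 0.71 with an estimated correlation). The chemokine gene Cxcl10 was higher (log2 fold change 1.82), as were Gbp5 (0.47) and Tapbp (0.29), and the GTPase gene Ifi47 was lower (−0.35). With the sex term, camera no longer called the type I interferon list (adjusted p = 0.0618), whose median log2 fold change was 0.19 against 0.25 by group alone, and without control replicate 1 it did not call the interferon gamma list (adjusted p = 0.0508).

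Replication-dependent histone genes were called lower as a list (camera adjusted p = 0.00934, and adjusted p = 0.71 with an estimated correlation). This list was fixed as a sign of RNA quality and library composition in these poly(A)-selected libraries. Whether its call reflects those or histone expression in the cells was not tested. Of 42 measured, 2 were lower and 40 not past the test (1 lower adjusted over the list alone). The gene with the smallest p, H1f0 (64.5 ± 4.2 against 141.3 ± 30.3 CPM, log2 fold change −1.13), encodes a linker histone made outside S phase that the symbol pattern also takes. Hist3h2ba had −1.57 at 0.38 against 1.2 CPM, and Hist1h2bc (−0.92) and Hist1h1a (−1.62) did not pass. With the sex term, without knockout replicate 3 and without control replicate 1 the list was not called (adjusted p = 0.355, 0.0749 and 0.192), and its median was −0.04 with the sex term against −0.37 by group alone.

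SWI/SNF subunit genes were not called as a list (camera adjusted p = 0.115, and 0.71 with an estimated correlation), but were called lower with no filter on low counts (0.0493) and with limma-voom (0.0422). Of 25 measured, Smarcc1, a core subunit, was lower (211.2 ± 3.1 against 252.7 ± 7.1 CPM, log2 fold change −0.26, SE 0.06, edgeR adjusted p = 0.0289, n = 3 each), and 24 did not pass (1 lower adjusted over the list alone). Actb had a log2 fold change of 0.32, Ss18 of −0.21 and Dpf3 of −1.36, with adjusted p of 0.061, 0.0779 and 0.0862, and the values of Actb and Dpf3 were 0.18 and −0.78 with the sex term.

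Lists for other cell types that the sort could have carried over were not called. B and plasma cell genes still leaned higher, with 10 of 12 positive and a median log2 fold change of 0.57. Medians were 0.07 for T and NK cell genes and −0.67 for mast cell and basophil and for stroma and endothelium genes. Mast cell and basophil genes had 2 lower of 7 measured, Cpa3 (log2 fold change −1.01) and Mcpt8 (−1.75), with a camera adjusted p of 0.0895 (3 lower adjusted over the list alone). That p became 7.55e-05 with the sex term, 0.015 without knockout replicate 1 and 8.88e-07 without control replicate 3, and 0.78 with an estimated correlation. B and plasma cell genes had 1 lower of 12 (Cd79b, −1.16; 1 adjusted over the list alone) and camera adjusted p = 0.445, T and NK cell genes 1 lower of 14 (Lat, −1.01; 2 adjusted over the list alone) and 0.43, and stroma and endothelium genes 1 lower of 9 (Emcn, −0.67; 2 lower and 1 higher adjusted over the list alone) and 0.306, or 0.0402 in female libraries alone.

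Cell cycle, growth and metabolic lists were not called either. NF-kB and inflammatory genes had 3 higher of 21, Relb, Ccl5 and Birc3 (camera adjusted p = 0.069; 6 higher and 1 lower adjusted over the list alone). That list was called with DESeq2 (adjusted p = 0.0428), with limma-voom (0.0422), with limma-voom and library weights (0.0274), without knockout replicate 1 (0.00285) and without control replicate 3 (0.0443). It was not called with an estimated correlation (0.71). S phase genes had 2 higher (Ccne1, Rrm2) and 3 lower (among them Cdca7 and Ung) of 43 (camera adjusted p = 0.773; 2 and 3 adjusted over the list alone). Of 26 p53 target genes 1 was higher (Rrm2b) and 2 lower (Perp, Tnfrsf10b), with camera adjusted p = 0.834 and 3 in each direction adjusted over the list alone. Hox genes and cofactors had 2 higher (Hoxb4, Hoxb5) and 1 lower (Meis1) of 19, with camera adjusted p = 0.924 (3 higher and 4 lower adjusted over the list alone). TGF-beta and BMP genes had 1 higher (Id2) and 2 lower (Ski, Smad3) of 23, with 0.834 (1 and 2 adjusted over the list alone), and glycolysis and hypoxia genes 2 lower (Pfkl, Pdk1) of 26, with 0.97 (2 adjusted over the list alone). Ribosomal protein genes had 1 lower (Rpl22l1) of 79, with 0.134 (0 adjusted over the list alone). No gene passed, over all genes or adjusted over the list alone, among 23 immediate early and heat shock, 53 G2 and M phase, 45 oxidative phosphorylation and 35 Myc and ribosome biogenesis genes, with camera adjusted p of 0.453, 0.134, 0.847 and 0.069. The Myc list had a median log2 fold change of −0.10, and −0.21 with the sex term. It was called in most alternatives, with a camera adjusted p of 0.0484 with upper-quartile scaling, 0.015 with no filter on low counts, 0.0428 with DESeq2, 0.00892 with limma-voom, 0.0148 with library weights and 4.24e-05 with the sex term. It was not called with DESeq2 size factors in edgeR (0.0719), with a stricter filter (0.0684) or with an estimated correlation (0.95), and with a library left out it ran from 0.00151 without control replicate 1 to 0.615 without control replicate 2. The G2 and M phase and ribosomal protein lists were called with limma-voom (0.0422 and 0.0295). With a library left out, G2 and M phase genes were called without knockout replicate 3 (0.00772) and control replicate 1 (0.0192), ribosomal protein genes without knockout replicate 2 (0.00141), and immediate early genes without knockout replicate 1 (0.0408) and control replicate 3 (0.00814). None of these lists was called with an estimated correlation (0.98 each).

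**Figure D3:**
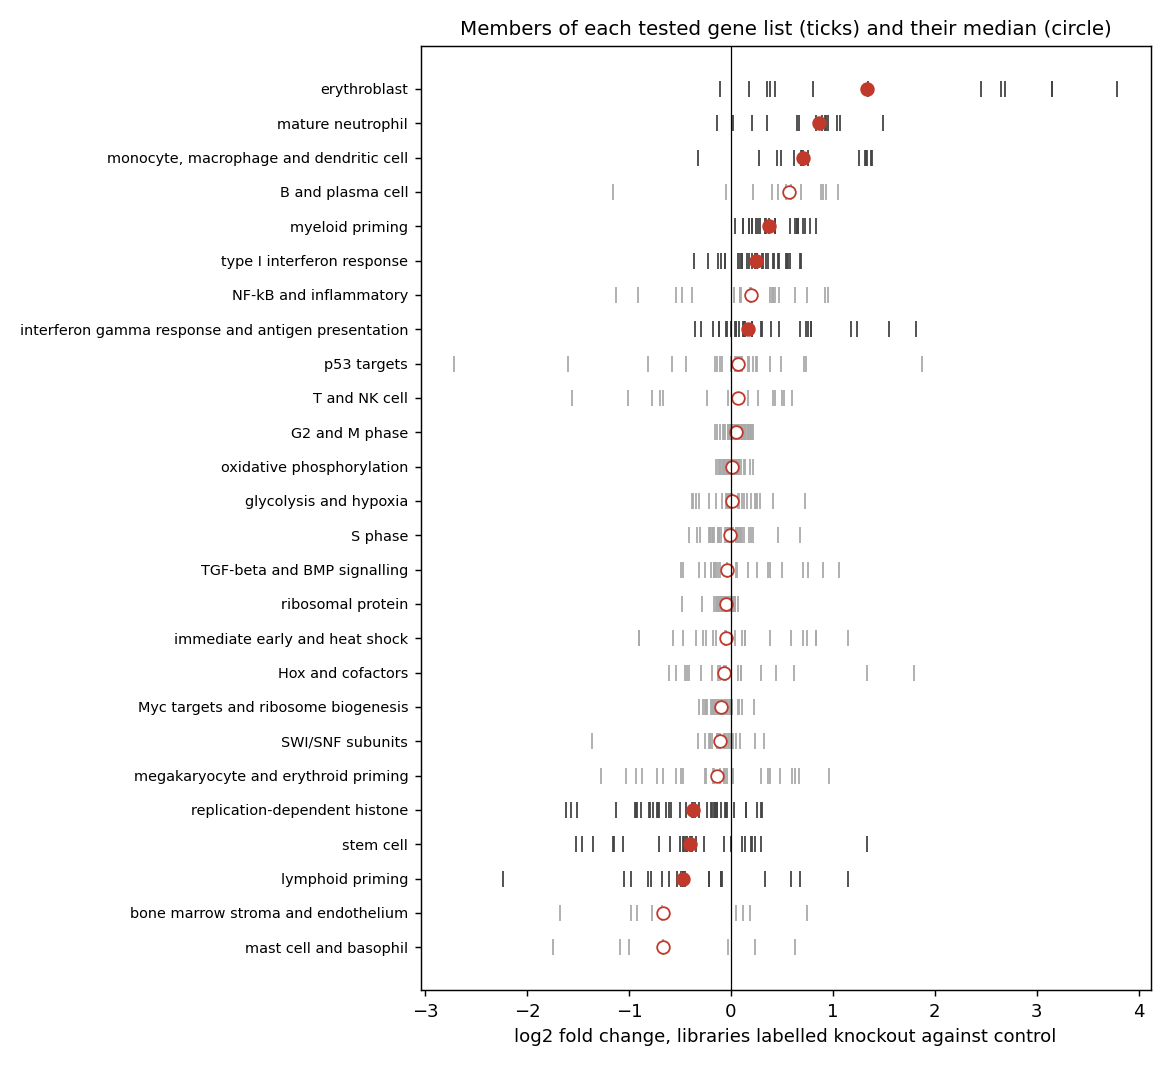
Log2 fold change of every measured member (ticks) of the 26 tested lists, libraries labelled knockout against control, with the median as a circle, filled where camera called the list at the preset correlation. Medians run from −0.67 to 1.34, and the 9 filled circles lie on both sides of 0.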

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

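With the fits on female libraries, the replicate block with a sex term, the sex term for lists and Arid2, and repeated rows counted once chosen after seeing the data, the counts of genes higher and lower (526 and 626) stayed within 1.5 times under both other scalings, both filters, limma-voom with and without weights, removal of ribosomal protein and sex-linked genes and repeated rows counted once. DESeq2 gave 833 higher. An adjusted p under 0.1 gave 951 and 1051, and a minimum absolute log2 fold change of 1 gave 134 and 201, by their construction. The sex term gave 7 and 36 genes and female libraries 10 and 29; both rest on control replicate 2 as the sole female control and the cause of the lower counts was not tested further. Replicate numbers were not taken to pair the libraries, since the labels tie them to no animal or batch. Correlations of deviations between same-numbered libraries were 0.29, 0.00 and 0.34. Control replicates 1 and 3 correlated best with their own numbers and control replicate 2 did not. On principal component 2 of log2 CPM (21.8% of the variance), replicates 1 to 3 lay at 19, 1.9 and −19.4 in the libraries labelled knockout. In controls they lay at 20.8, 4.6 and −26.9. The order is the same in both groups, with replicate 2 in the middle, where little deviation is left to correlate. A link between same-numbered libraries therefore stays open. The replicate block gave 1169 higher and 1003 lower genes, and the block with a sex term 420 and 376; the cause was not tested. Leaving out each library in turn gave 119 to 440 genes higher and 171 to 544 lower, lowest without knockout replicate 2 and highest without control replicate 2, with fewer libraries to test. The 9 lists called became 14 with limma-voom, 0 with camera at an estimated correlation and 0 with fry (1 and 5 lists at an unadjusted p under 0.05), and 9 to 13 with a library left out; the cause was not tested. Arid2, never past the test, had log2 fold changes of −0.022 with upper-quartile scaling, −0.002 with no filter, −0.022 with library weights and −0.036 with the block and sex term, and −0.032 to 0.044 with a library left out. Lists that were never called in the main test changed sign in some settings: glycolysis and hypoxia (adjusted p = 0.936 with no filter, 0.947 with DESeq2, 0.842 with library weights, 0.481 with the sex term, 0.447 in females, 0.304 with block and sex term), oxidative phosphorylation (0.889 with weights, 0.862 with the sex term, 0.74 in females), Hox genes (0.951 with weights, 0.642 with the sex term, 0.664 in females, 0.707 with block and sex term) and ribosomal protein genes, which block and sex term called higher (0.00555). With a library left out the adjusted p of the lists that changed sign ran from 0.466 to 0.927 for glycolysis, 0.243 to 0.927 for oxidative phosphorylation, 0.656 to 0.998 for Hox, 0.00141 to 0.646 for ribosomal protein, 0.332 to 0.993 for S phase, 0.00772 to 0.969 for G2 and M phase, 0.425 to 0.998 for p53, 0.00814 to 0.967 for immediate early and 0.000207 to 0.824 for megakaryocyte and erythroid genes. Of the named genes and lists, 52 lost their call with the sex term, 49 in females, 15 with block and sex term (lymphoid priming among them, adjusted p = 0.707; type I interferon stayed called, 0.000268), 1 with DESeq2, 4 with limma-voom, 2 with library weights, 1 with no filter, 11, 22 and 15 without knockout replicates 1 to 3 and 17, 5 and 8 without control replicates 1 to 3. The block alone called the Myc list and the megakaryocyte and erythroid list (0.0245 each) and the mast cell list (0.00664). Depth ran from 12408966 to 28185678 reads per library, and folds of genes near 1 CPM rest on few reads.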

Other observations

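The tests of windows, of the position of single libraries, of marker lists against each other and of other splits were chosen after the results were seen, as was the sex term for single genes, and the genes named here that are in no earlier list were chosen after their values were seen. In the libraries labelled knockout, Smo, the transducer of hedgehog signals, had 29.2 ± 0.41 against 78.7 ± 11.3 CPM (log2 fold change −1.43, SE 0.10, edgeR adjusted p = 0.00143, n = 3 each) and Kif7 1.4 ± 0.22 against 9.3 ± 1 CPM (−2.67, adjusted p = 0.00149), so that both were lower, and both stayed past the threshold with the sex term (adjusted p = 0.0252 each). Hmox1, a haem-degrading enzyme, had 90.1 ± 45 against 23.7 ± 8.1 CPM (1.93), and Lpl (1.62), Cd14 (1.61), Nr1h3 (1.54), Cd86 (1.29) and Trem2 (0.94) were higher as well, with adjusted p from 0.00623 to 0.0441. None of these 6 passed with the sex term, where their log2 fold changes were 0.86 to 1.99 and their SEs 0.29 to 0.61 in place of 0.19 to 0.38, so the lost calls do not show that these changes follow sex. All 6 rose from knockout replicate 1 to 3, with Hmox1 at 47.2, 86 and 137 CPM. Marco (7.9, 10.6 and 22.55 CPM) and the globin gene Hbb-bs (36.4, 56.2 and 109.8 CPM) rose in the same order. In controls, Hmox1 (16.2, 22.5 and 32.4 CPM), Cd14 and Cd86 also rose from replicate 1 to 3, while Lpl, Nr1h3, Trem2, Marco and Hbb-bs did not. The order is thus not particular to the libraries labelled knockout for every gene, and its cause was not tested.

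Called genes were tested for lying near each other in 397 windows of 5 Mb with at least 10 tested genes. For genes higher, the window with the lowest p was chromosome 1 from 170 to 175 Mb, with 11 of 73 genes called (hypergeometric adjusted p = 0.0394): Fcgr2b, Fcer1g, Cd84, Slamf9, Pyhin1, Ifi204, Ackr1, Cadm3, Igsf9, Olfml2b and Pcp4l1. Cadm3 overlaps Ackr1 on the same strand and Aim2 on the opposite one (960, 139 and 7170 reads in all), and how reads in the overlaps were counted is not given in the sources used here. For genes lower it was chromosome X from 135 to 140 Mb, with 7 of 29 genes (Bhlhb9, Ngfrap1, Tceal5, Gprasp2, Tceal1, Bex1 and Gprasp1), which did not pass (adjusted p = 0.107). The window edge at 135 Mb leaves out the neighbours Sytl4 (log2 fold change −1.70), Armcx4 (−1.43) and Armcx2 (−0.81). In female control replicate 2 these had 11.9, 23.8 and 43.1 CPM, against at most 4.8, 13.3 and 25.7 CPM in the female libraries labelled knockout. A further window for genes higher, chromosome 3 from 125 to 130 Mb, had 5 of 16 genes called, among them Ugt8a, Alpk1, Tifa and Ccdc109b, with an adjusted p that rounds to 0.05. The adjustment covered the windows of each direction separately, and the hypergeometric test takes genes as independent of each other. That neighbouring genes change together therefore stays open, for the window on chromosome 1 as for the window on X.

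The 1152 genes called and the sexes of the animals overlap in the design. Among 920 autosomal genes called without control replicate 2, that female library lay at a median of 0.32 of the way from the male controls (0) to the libraries labelled knockout (1), with quartiles of 0.14 and 0.51. Left out in the same way, control replicates 1 and 3 lay at 0.07 and −0.04 and knockout replicates 1 to 3 at 0.84, 0.91 and 0.93. Those values come from other sets of genes, called with the female control still among the controls, so they are no baseline for 0.32. Sex as the whole cause would place control replicate 2 near 1, but the value of 0.32 rests on a single female control. How much of the change follows sex therefore stays open, and part of it may. Deletion of Arid2, which the design names, stays open and untested here.

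In the libraries labelled knockout, the mature neutrophil, erythroblast and monocyte, macrophage and dendritic cell lists were called higher by camera (7 of 14, 7 of 13 and 4 of 15 genes; adjusted p = 0.71 for each with an estimated correlation), and the B and plasma, T and NK and mast cell and basophil lists were not called. An even rise of all other cell types would raise the markers of each alike. Mature neutrophil and mast cell and basophil genes instead had medians of 0.86 and −0.67, a difference of 1.53 (exact permutation test over genes, two-sided p = 0.00072, 14 and 7 genes, which are not independent). The mean log2 CPM of neutrophil minus mast cell genes was 2.39 to 2.63 in the libraries labelled knockout and 0.79 to 1.9 in controls. These lists did not rise alike, but the pair was chosen after its values were seen. The median of −0.67 was the lowest of the tested lists, shared with stroma and endothelium genes. A small permutation p is likely for a pair so chosen, so no conclusion on an even rise is drawn from it. Nor can the comparison decide on a lower share of the sorted cells that comes from particular cell types, whose markers alone would rise. Carry-over of particular mature cells, which the lineage gate should remove, and a change within the sorted cells both stay open.

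Mmrn1 had 0 reads in control replicate 2 and 268 to 379 in the other libraries. It was not called by group alone (edgeR adjusted p = 0.751) and was called with the sex term (0.0151), which rests on that library.

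Other splits of the 6 libraries into 3 and 3 number 10 with the real split, too few for a share under 0.05. The real split called 526 genes higher and 626 lower, and the highest of the other splits 0 in either direction. For gene lists the real split called 9 and the highest other split 18, and 6 of the 10 splits called at least 9.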
